A study of Mus musculus with 4 samples.

How the data were processed

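RNA from cultured mouse keratinocytes was hybridised to MoGene 2.0 whole-transcript arrays, 2 per genotype. Single-stranded cDNA was made from amplified cRNA, fragmented and labelled with biotin, per the labels' protocols. The deposited values are on the log2 scale, 1 per transcript cluster, and were made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects the background, sets the arrays to a common distribution by quantile normalization and summarises the probes of a cluster. It thereby removes any difference between arrays in total signal, so all changes are relative to the other genes. Software versions and the RMA settings are not given in the sources used here. The scale was taken from the values, which run from 1.33 to 13.4 with quartiles that differ by less than 0.1 between arrays. No scanner files, detection calls or slide positions were used here, so a limit of detection per row and batches of hybridisation could not be examined.

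The table holds 41345 rows. The platform annotation gives exactly 1 gene symbol for 23521 rows, several for 1814 and none for 16010. Symbols were checked through the gene identifier in the reference gene table of assembly GRCm38.p6, which held 23328 of the 23521 rows (99.2%), and 0 symbols changed. Rows with 1 symbol entered the tests. For the 1082 genes with more than 1 row, the row with the highest mean over the 4 arrays stood for the gene, which left 22180 genes. Rows with several symbols or none did not enter the main fit. Some list members have no value, and these were not traced to a particular kind of row. No filter on dim rows was applied in the main fit. The sources used here do not name a genome build for the array values, so no coordinates are given.

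Differences between the genotypes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, 2 residual degrees of freedom per gene and a fitted prior worth 2.95), Glut1-deficient minus wild type, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A gene rose or fell when it passed. A single value cannot be tested by permutation here, since 2 against 2 arrays allow no two-sided exact p below 0.333. Each array is a pool of 2 plates. The labels call the arrays biological replicates, and nothing beyond that says how far the pools of a genotype share mice or days, so p-values measure the spread between these pools. Replicate arrays were not duplicates: the wild-type pair had r = 0.9962 over genes and the Glut1-deficient pair r = 0.9951, against 0.9866 to 0.9909 between genotypes.

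Fixed before the data were examined were 26 gene lists, 12 lists of markers of other cell types, the tests and the rule for named genes. The rule took Slc2a1, the 12 largest rises and the 12 largest falls among genes that passed with both arrays of a genotype on the same side of both of the other, up to 4 members of each list with the smallest p, and up to 3 members of each cell type list with the highest mean. Predicted genes, olfactory receptors and small RNAs were skipped among the largest changes (38 of the changed genes). Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. The preset correlation treats list members as nearly independent, whereas the estimated one rests on 2 residual degrees of freedom. Gene lists and cell type lists were adjusted as separate families. A few genes belong to 2 lists, such as Slc7a11, Sphk1, Angptl4, Fabp4 and Thy1.

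The fit was tested on simulated arrays with the real means of the 22180 genes and 200 changed genes. It recovered 0 of 50 genes changed by 0.5, 28 of 50 changed by 1, 50 of 50 changed by 2 and 49 of 50 changed by 3 on the log2 scale, with 10 of 137 calls false. In this simulation, changes below about 1 on the log2 scale were thus often missed with 2 arrays per genotype. The cutoff of the adjustment depends on the share of changed genes. The real arrays had 4923 genes at unadjusted p under 0.05 in limma, so recovery there can differ. A list of 25 genes shifted by 0.5 was called by camera with the preset correlation and missed with an estimated one (adjusted p = 0.103), and 0 of 15 unshifted lists were called. The simulated genes were drawn independently, so this cannot show how often the preset correlation calls lists of correlated genes falsely. Alternatives were an intensity trend without and with robust estimation, 3 other normalizations of the deposited values, a filter on dim genes, all rows as separate tests, the mean of a gene's rows, leaving out each array, the replicate number as a block, other thresholds, a plain pooled-variance statistic and the other list tests. Figures were drawn with matplotlib 3.10.9.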

Results

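Gene expression was measured in primary mouse keratinocytes, the epithelial cells of the epidermis, cultured from 1-week-old C57BL/6J mice. Wild-type cells came from mice with floxed Glut1 alleles, and Glut1-deficient cells from floxed mice that also carried Cre under the keratin 14 promoter, which is active in basal keratinocytes. Glut1 is the glucose transporter encoded by Slc2a1, so the comparison asks how keratinocyte transcription differs when glucose import through Glut1 is removed. Each genotype had 4 mice. Cells were reseeded at equal number after 3 days, harvested 1 day later, and 2 plates of a genotype were combined for each array, which gave 2 arrays per genotype. For extraction, 1500000 wild-type and 1000000 Glut1-deficient cells were lysed per sample. Values are log2 intensities per transcript cluster on the MoGene 2.0 array, and 22180 named genes were tested. The 4 arrays had medians between 4.07 and 4.11. The number of arrays limits the precision, and no depth applies to intensities.

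The deleted gene was examined before any other. The brighter of the 2 rows named Slc2a1 had a log2 value of 11.09 ± 0.056 (SD, n = 2) on the wild-type arrays and 11.01 ± 0.003 (SD, n = 2) on the arrays labelled Glut1-deficient. The log2 fold change was -0.075 with a 95% interval of -0.30 to 0.15 (limma adjusted p = 0.675), so Slc2a1 was not shown to differ. A dimmer row read 5.14 ± 0.060 and 4.62 ± 0.251 (SD, n = 2 each), a log2 fold change of -0.52 with a 95% interval of -0.94 to -0.10 (limma unadjusted p = 0.0256, adjusted p = 0.247 over all rows). The sources used here do not say which exons were deleted or where the probes of each row lie, so these rows neither bear out nor contradict the genotype labels. The deficient genotype is therefore named by its label throughout. Of the 13 glucose transporter genes tested, Slc2a5, a fructose transporter, fell by 0.73 on the log2 scale (SE 0.110), 0 rose and 12 did not pass (0 rose and 2 fell adjusted over the list alone). Slc2a12 had a log2 fold change of -0.57 and Slc2a10 of 0.39, and neither passed over all genes.

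Many genes differed between the arrays labelled Glut1-deficient and the wild-type arrays, and the largest rises exceeded the largest falls. Both are ranked among genes that passed and that the rule for named genes did not skip. B4galnt2, a glycosyltransferase that adds N-acetylgalactosamine to cell-surface glycans, rose 34.8-fold, from 4.56 ± 0.297 to 9.68 ± 0.180 (SD, n = 2 each; limma adjusted p = 0.00743). Car6, a secreted carbonic anhydrase, rose 10.5-fold. Efhd1, which encodes a mitochondrial calcium-binding protein, rose 8.99-fold. Ddit3, the stress transcription factor CHOP, rose 6.98-fold, and Acot2, a mitochondrial acyl-CoA thioesterase, rose 6.02-fold. The other genes among the 12 largest rises were Fam171b, Dthd1, Dhrs9, Exph5, Slc43a3, Ddr2 and Cox6a2, with rises between 5.61-fold (Cox6a2) and 8.05-fold (Fam171b). Among such genes the largest fall was that of Txnip, an arrestin-related gene whose transcription is known to follow intracellular glucose metabolites. It was 5.01-fold lower, at 8.53 ± 0.080 on wild-type arrays and 6.20 ± 0.399 on the arrays labelled Glut1-deficient (SD, n = 2 each; limma adjusted p = 0.0207). Fat2, an epidermal atypical cadherin, was 4.16-fold lower. Igfbp3, an insulin-like growth factor binding protein, was 4.06-fold lower, and the matrix genes Tgfbi and Thbs1 were 3.57-fold and 3.54-fold lower. Slitrk6, Mill1, Flrt1, Nuak1, Apol9b, Tmem176a and Cnksr2 completed the 12 largest falls, which ranged down to 3.38-fold (Cnksr2). In all, 630 genes passed (limma, Benjamini-Hochberg adjusted p under 0.05), of which 397 rose and 233 fell, and 182 rose and 78 fell by a factor of at least 2. With any 1 array left out, which leaves 1 residual degree of freedom, 0 genes passed in limma (2948 to 4627 genes at unadjusted p under 0.05), while the log2 fold change of B4galnt2 stayed between 4.91 and 5.33 and that of Txnip between -2.61 and -2.04. The count was 2671, with 1344 rises and 1327 falls, when the variance was allowed to follow intensity, and 0 when all 41345 rows were tested (limma, 6694 rows at unadjusted p under 0.05). Nothing in the labels shows whether plates of the 2 genotypes were handled in separate batches.

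**Figure D1:**
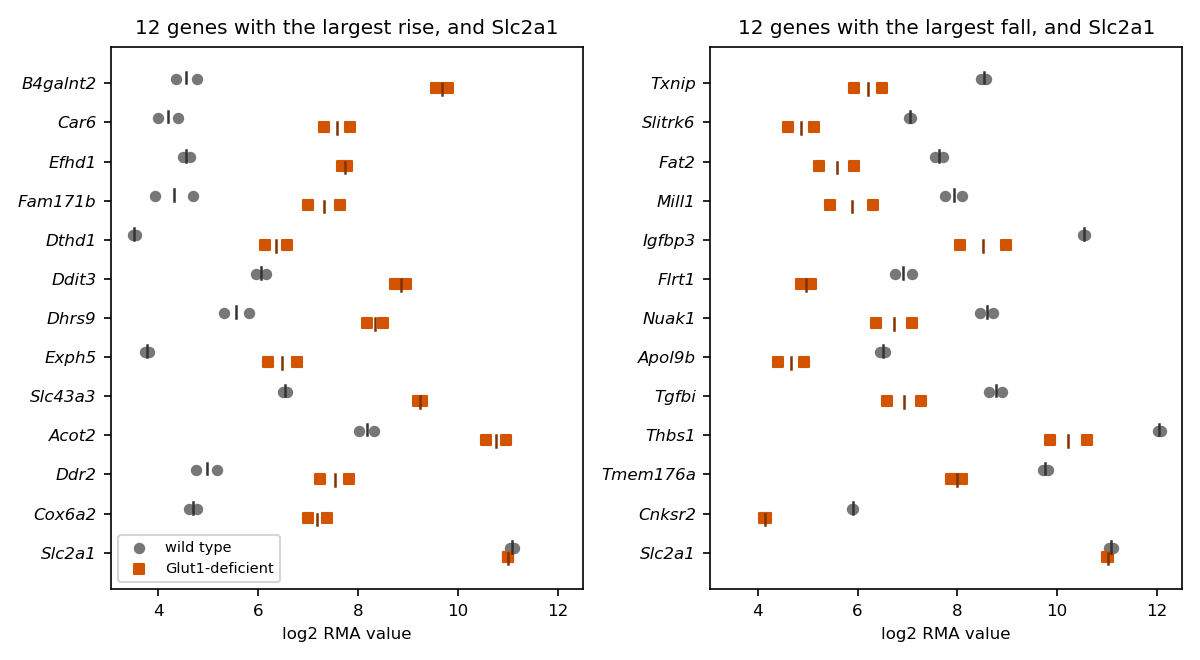
Log2 RMA values (horizontal axis) of the 12 genes with the largest rise (left), the 12 with the largest fall (right) and Slc2a1 (both), with 1 point per array (2 wild-type circles, 2 Glut1-deficient squares) and vertical ticks at the group means. The 24 changed genes were chosen among those whose groups do not overlap, and the Slc2a1 means are 11.09 and 11.01.

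Genes of the integrated stress response, which are induced through the transcription factor ATF4 under amino acid or other metabolic stress, were higher on the arrays labelled Glut1-deficient. Of 22 tested members, 21 had positive log2 fold changes, 14 rose, 0 fell and 8 did not pass (20 rose and 0 fell adjusted over the list alone), and the median log2 fold change was 0.82. Besides Ddit3, the glutathione-degrading enzyme Chac1 rose 4.43-fold, the cystathionine gamma-lyase gene Cth 2.99-fold and the secreted glycoprotein gene Stc2 3.74-fold. The list was higher than other genes by limma's camera test (adjusted p = 2.99e-19; adjusted p = 0.41 with an estimated correlation). Amino acid transport genes moved the same way, with 6 of 13 tested members risen, 0 fallen and 7 not past the test (10 rose and 1 fell adjusted over the list alone). The cationic amino acid transporter Slc7a3 rose 4.54-fold, the neutral amino acid transporter Slc1a4 3.27-fold, Slc7a1 2.04-fold and Slc7a5 1.90-fold, and the list median was 0.93 (camera adjusted p = 5.72e-08; adjusted p = 0.41 with an estimated correlation). In the list of pentose phosphate and serine synthesis genes, 6 of 14 members rose, 0 fell and 8 did not pass (9 and 0 adjusted over the list alone). The members with the smallest p were serine and one-carbon genes, namely Aldh1l2 (4.44-fold), Mthfd2 (2.66-fold), Psph (2.02-fold) and Shmt2 (1.75-fold), and the list median was 0.52 (camera adjusted p = 4.11e-05; adjusted p = 0.41 with an estimated correlation). On the same arrays the fibroblast marker list had a median of 0.96 and the melanocyte marker list one of 0.33.

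Genes of central carbon and mitochondrial energy metabolism showed few shifts in 1 direction as groups, which is what camera tests. Members that move both ways escape it. The fry test for changes in either direction gave adjusted p from 0.00859 to 0.0247 for the lists of this paragraph. Every gene list except G2/M and mitosis (adjusted p = 0.0795) passed that test, so these values are not particular to energy metabolism. The oxidative phosphorylation list passed it (adjusted p = 0.0101) with 0 members past limma's test. Among 20 glycolysis genes tested, 1 rose, 1 fell and 18 did not pass (4 rose and 3 fell adjusted over the list alone). Gpi1, Pfkfb1, Aldoa and Eno1 of that list were not tested. The lactate exporter Slc16a3 was at 8.68 ± 0.032 and 7.65 ± 0.032 (SD, n = 2 each), which was 2.05-fold lower, while the monocarboxylate transporter Slc16a1 rose 1.53-fold. The log2 fold changes of Pfkfb2 (0.46) and Pfkfb3 (0.79) did not pass. The list median was 0.01 (camera adjusted p = 0.891; adjusted p = 0.897 with an estimated correlation). In the tricarboxylic acid cycle list Idh2 rose 1.75-fold and the other 24 tested genes did not pass (3 rose and 0 fell adjusted over the list alone). Its median of -0.04 and mean of 0.04 differed in sign (camera adjusted p = 0.882). None of 42 nuclear genes of oxidative phosphorylation passed, over all genes or adjusted over the list alone (limma, 0 calls). Their median was 0.003 and the middle 50% of their log2 fold changes lay between -0.09 and 0.10 (camera adjusted p = 0.861). In the fatty acid oxidation list, Acot2 and Fabp4 (2.56-fold) rose, Angptl4 fell by 0.56 on the log2 scale and 22 of 25 did not pass (2 rose and 1 fell adjusted over the list alone). Its median of -0.01 and mean of 0.13 differed in sign, and its median was 0.009 after median centring (camera adjusted p = 0.882). Acot1, a close paralogue of Acot2 whose transcripts are similar enough to share probes with it, had a log2 fold change of 0.45 that did not pass. Of 20 fatty acid synthesis genes, 1 fell, the desaturase Fads2 (by 0.64 on the log2 scale), 0 rose and 19 did not pass (0 and 1 adjusted over the list alone; camera adjusted p = 0.63). Sterol synthesis genes lay lower as a group, although 0 of 19 members passed over all genes in limma (0 rose and 2 fell adjusted over the list alone). Their median was -0.20, with Hmgcs1 at -0.43 and Tm7sf2 at -0.49 (camera adjusted p = 0.000298; adjusted p = 0.492 with an estimated correlation). The fibroblast and melanocyte marker lists had medians of 0.96 and 0.33 on the same arrays.

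Proliferation genes were lower on the arrays labelled Glut1-deficient, and every tested member of both lists had a negative log2 fold change. Of 27 S phase and DNA replication genes, 3 fell, 0 rose and 24 did not pass (23 fell adjusted over the list alone), with a median of -0.62. The replication licensing factor Cdc6 fell by 1.31, thymidylate synthase Tyms by 0.62 and the helicase subunit Mcm7 by 0.66 on the log2 scale (camera adjusted p = 6.28e-13; adjusted p = 0.492 with an estimated correlation). Of 29 genes of the G2/M phases, Kif23, a kinesin of cytokinesis, fell by 0.99, 0 rose and 28 did not pass (21 fell adjusted over the list alone). Mki67, the proliferation marker Ki-67, had a log2 fold change of -0.94 (limma adjusted p over all genes above 0.05). The list median was -0.56 (camera adjusted p = 3.58e-12, and 0.558 with an estimated correlation). Neither list passed fry's test for a shift in 1 direction (adjusted p = 0.0959 for S phase and 0.148 for G2/M). Relative to the wild-type mean, the S phase median was -0.74 on Glut1-deficient array 1 and -0.46 on array 2, the G2/M median -0.74 and -0.38, and that of the fibroblast markers 1.18 and 0.66. Among p53 targets and cell cycle inhibitors, 1 of 20 rose, Cdkn1c (1.95-fold), 0 fell and 19 did not pass (1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.63).

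Markers of keratinocyte differentiation split by gene. In the suprabasal and cornified envelope list, 5 of 37 members rose, 2 fell and 30 did not pass (13 rose and 2 fell adjusted over the list alone), with a median of 0.24, or 0.155 without Glut1-deficient array 2 (camera adjusted p = 0.0268). Cdsn, the corneodesmosome protein, rose 5.52-fold, Sbsn 1.98-fold and the transcription factor Klf4 1.84-fold, while Ivl, the envelope precursor involucrin, fell by 1.58 on the log2 scale (camera adjusted p = 0.00104; adjusted p = 0.492 with an estimated correlation). Sphingolipid and ceramide genes, which serve the epidermal barrier, rose in 3 of 27 cases, with 0 falls and 24 not past the test (13 rose and 1 fell adjusted over the list alone). These were the lipid transporter Abca12 (4.56-fold), the lipoxygenase Aloxe3 (2.88-fold) and the serine palmitoyltransferase subunit Sptlc3 (2.01-fold), and the list median was 0.29 (camera adjusted p = 9.78e-06; adjusted p = 0.41 with an estimated correlation). Basal keratinocyte and adhesion genes had a median of -0.28, with 0 of 16 past the test over all genes in limma (1 rose and 9 fell adjusted over the list alone; camera adjusted p = 0.000687; adjusted p = 0.558 with an estimated correlation). Dst, a hemidesmosome linker gene with the smallest p of the list, was at 0.57 on the log2 scale, Itgb4 at -0.57, Lamb3 at -0.65 and Col17a1 at -0.73. Genes of the stress keratin, alarmin and wound list went both ways. Of 25, 3 rose, among them the growth factor Ereg (2.43-fold), the urokinase receptor Plaur (1.86-fold) and the metalloproteinase Mmp3 (3.74-fold), 4 fell, among them the keratin Krt6b (by 1.28 on the log2 scale), and 18 did not pass (8 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.861). Mmp3 is also a fibroblast gene, and the fibroblast marker list had a median of 0.96 on these arrays.

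**Figure D2:**
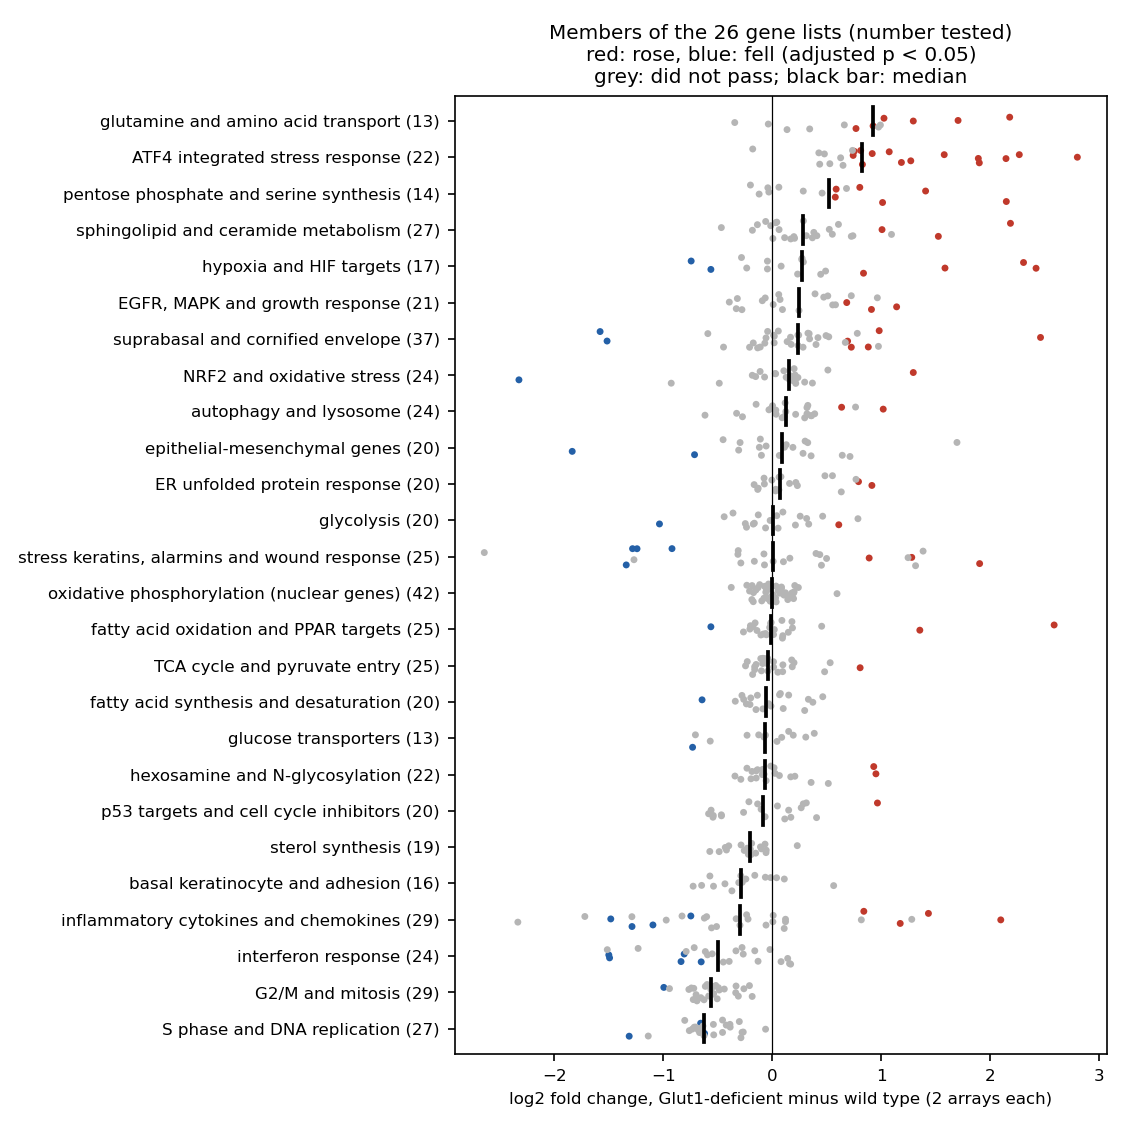
Log2 fold changes (horizontal axis, Glut1-deficient minus wild type, 2 arrays each) of the tested members of each of the 26 gene lists, 1 point per gene, with red and blue for genes that rose or fell (limma adjusted p under 0.05), grey for those that did not pass and a black bar at the list median. The medians run from -0.62 for S phase genes to 0.93 for amino acid transport genes.

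Interferon response genes were lower on the arrays labelled Glut1-deficient. Of 24 tested, 5 fell, 0 rose and 19 did not pass (16 fell and 0 rose adjusted over the list alone). Isg15, an interferon-induced ubiquitin-like protein, fell by 1.50, the oligoadenylate synthetase-like gene Oasl2 by 1.49, Psmb8, an immunoproteasome subunit, by 0.84 and Xaf1 by 0.81 on the log2 scale. The list median was -0.50 (camera adjusted p = 2.93e-07, and 0.41 with an estimated correlation). The interferon list did not pass fry's test for a shift in 1 direction (adjusted p = 0.0537). Inflammatory cytokine and chemokine genes went both ways, with 4 of 29 risen, 4 fallen and 21 not past the test (5 rose and 13 fell adjusted over the list alone). The neutrophil chemokine Cxcl5 fell by 1.29 on the log2 scale, whereas the cyclooxygenase Ptgs2 rose 2.26-fold, the chemokine Ccl7 4.28-fold and the epithelial cytokine Tslp 2.71-fold. The list median was -0.29 (camera adjusted p = 0.0214; adjusted p = 0.624 with an estimated correlation). Fibroblasts also express Ccl7, and the fibroblast marker list had a median of 0.96 on these arrays. In the EGFR and MAPK response list 3 of 21 rose, 0 fell and 18 did not pass (11 rose and 4 fell adjusted over the list alone). The feedback regulators Dusp5 (1.88-fold), Spry2 (1.61-fold) and Spry4 (2.21-fold) were those that rose (list median 0.25; camera adjusted p = 0.00392; adjusted p = 0.492 with an estimated correlation).

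Of 20 genes of the endoplasmic reticulum unfolded protein response, 2 rose, Herpud1 (1.89-fold) and Xbp1 (1.73-fold), 0 fell and 18 did not pass (6 rose adjusted over the list alone), with Hspa5 at a log2 fold change of 0.77. The list median was 0.07 (camera adjusted p = 0.00979; adjusted p = 0.624 with an estimated correlation), and the call was lost without Glut1-deficient array 1 (camera adjusted p = 0.0773), while the median was 0.141 without array 2 of that genotype. Hypoxia-associated genes rose in 4 cases of 17, fell in 2 and did not pass in 11 (8 rose and 3 fell adjusted over the list alone). The peptide hormone gene Adm rose 5.36-fold, Lox, a collagen cross-linking enzyme, 4.95-fold and Car12 3.01-fold, while the HIF prolyl hydroxylase Egln3 fell by 0.74 on the log2 scale (list median 0.27; camera adjusted p = 0.0214; adjusted p = 0.699 with an estimated correlation), and the list did not pass among genes above the median level (camera adjusted p = 0.0604). Lox is also a fibroblast gene and rose beside the fibroblast marker list (median 0.96). Autophagy and lysosome genes had 2 of 24 risen, Mcoln1 (1.56-fold) and Hexa (2.03-fold), 0 fallen and 22 not past the test (8 rose and 1 fell adjusted over the list alone; list median 0.12; camera adjusted p = 0.00602; adjusted p = 0.41 with an estimated correlation). The median was 0.216 without wild-type array 2 and 0.185 without Glut1-deficient array 2. Pigment cells hold many lysosome-related organelles, and the melanocyte marker list had a median of 0.33 on the same arrays. In the NRF2 and oxidative stress list 1 of 24 rose, the cystine transporter Slc7a11 (2.46-fold), 1 fell, Txnip, and 22 did not pass (2 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.188). Of 22 hexosamine and N-glycosylation genes, Gnpnat1 (1.91-fold), an enzyme of UDP-N-acetylglucosamine synthesis, and Ogt (1.94-fold), the O-GlcNAc transferase, rose, 0 fell and 20 did not pass (3 rose adjusted over the list alone). That list had a median of -0.07 and a mean of 0.06, which differ in sign (camera adjusted p = 0.95). In the epithelial-mesenchymal list, 0 of 20 rose, Tgfbi and Acta2 (by 0.71 on the log2 scale) fell, and 18 did not pass (5 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.63). Vim, the intermediate filament of mesenchymal cells, had a log2 fold change of 1.70 with SE 0.330 that did not pass. Of the 26 lists, 15 passed the camera test with its preset correlation and 0 with an estimated one.

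Markers of other cell types were examined because primary epidermal cultures can hold non-keratinocytes. Melanocyte markers were higher on the arrays labelled Glut1-deficient, with 5 of 11 risen, 0 fallen and 6 not past the test (6 rose adjusted over the list alone). The pigment genes Dct, Pmel and Tyrp1 rose 3.42-fold, 3.24-fold and 2.49-fold (list median 0.33; camera adjusted p = 0.000103; adjusted p = 0.876 with an estimated correlation). The list lay 0.51 above the wild-type mean on Glut1-deficient array 1, which is also its median without array 2, and 0.31 above it on array 2. Among dermal fibroblast markers, 1 of 14 passed over all genes, the matrix glycoprotein Sparc (2.37-fold), 0 fell and 13 did not pass (10 rose and 1 fell adjusted over the list alone), with a list median of 0.96 (camera adjusted p = 9.15e-06; adjusted p = 0.876 with an estimated correlation). Pdgfra had a log2 fold change of 2.15 with SE 0.381 and Fbln1, an abundant matrix gene of fibroblasts, one of -0.61 with SE 0.141, and neither passed; the fibroblast list lay 1.18 above the wild-type mean on Glut1-deficient array 1 and 0.66 above it on array 2. Ddr2, one of the 12 largest rises, is a collagen receptor typical of mesenchymal cells. The other lists tested, for Langerhans cells and macrophages (camera adjusted p = 0.804), T cells (0.975), mast cells (0.86), endothelial and vascular cells (0.804), hair follicle (0.804), sebocytes (0.975), Merkel cells (0.975), skeletal muscle (0.804) and adipocytes (0.122), did not pass. Single risen members among these were Kdr (5.21-fold) of the endothelial list, Cidea (1.95-fold) of the sebocyte list and Fabp4 of the adipocyte list. Of the erythroid list 1 gene, Slc4a1, was tested, at a log2 fold change of -0.24.

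**Figure D3:**
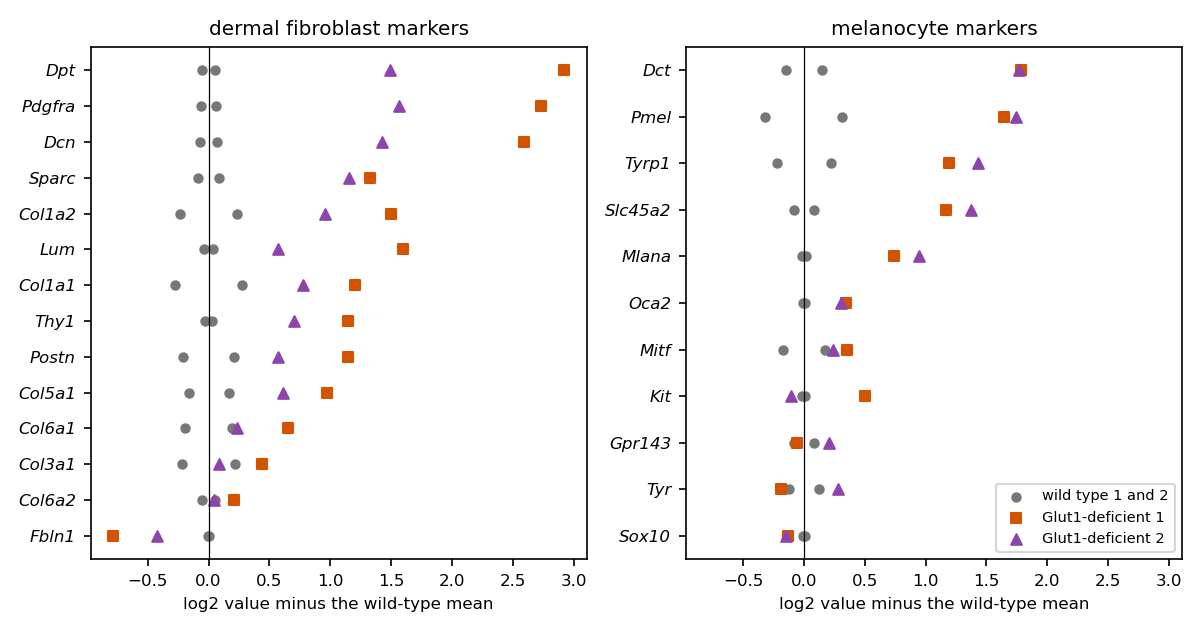
Log2 value minus the wild-type mean (horizontal axis) of each dermal fibroblast marker (left) and melanocyte marker (right), with 1 point for each of the 2 wild-type and 2 Glut1-deficient arrays. Of 14 fibroblast markers, 13 lie higher on Glut1-deficient array 1 than on array 2, against 5 of 11 melanocyte markers.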

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

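Of 630 changed genes, 615 to 628 were called again after another quantile normalization, median centring or cyclic loess (643 to 740 calls), and all 87 named genes that had passed kept their direction and call under these 3. The count rose to 2671 with an intensity trend and 2729 with robust estimation as well, both of which included all 630, to 2327 among genes above the median level, and to 1855 at an adjusted p under 0.10. With a trend 50.3% of calls were rises, against 63.0% without. It fell to 0 with all rows of the table tested (limma, 6694 rows at unadjusted p under 0.05), to 0 with a plain pooled-variance statistic (3646 genes at unadjusted p under 0.05), and to 0 in each of the 4 fits that left out 1 array (range 0 to 0). For these changes the cause was not tested, apart from the single residual degree of freedom that 3 arrays leave. With the replicate number as a block, 37 genes passed, 32 of them rises. Deviations of same-numbered arrays correlated at r = -0.025, so no shared shift of these arrays showed. Whether the numbers mark a shared litter, day or hybridisation is not known. Of the 87 named genes that had passed, 16 passed with the replicate block. Of 69 named genes that had not passed, Slc2a1 aside, 39 passed with an intensity trend. Among genes above the median level 39 of them passed and 19 did not, and the rest fell below that filter. Median centring gave 7 such gains, cyclic loess 7 and another quantile normalization 3. The log2 fold change of Slc2a1 stayed between -0.297 (mean of its rows) and -0.035 and never passed. Gene lists past the threshold numbered 14 or 15 in every camera fit with the preset correlation, 0 with an estimated correlation (6 lists had adjusted p = 0.41, the lowest) and 4 with fry. The 4 lists past fry's test were those of ATF4, amino acid transport, sphingolipid, and pentose phosphate and serine synthesis genes. Of cell type lists, 2 passed with the preset correlation, 0 with an estimated correlation and 0 with fry. Lost calls were the unfolded protein response list without Glut1-deficient array 1 and the hypoxia list among genes above the median level (camera adjusted p = 0.0604), where the adipocyte list was gained (0.0394). Over 11 alternatives with the preset correlation the adjusted p ran from 0.00442 to 0.0773, from 0.00823 to 0.0604 and from 0.0394 to 0.265 for these 3 lists in turn. None of the 87 called genes that were named and no called list changed direction; the other called genes were not followed, and 35 values called in neither fit changed sign. Lists were not run with robust estimation, which camera lacks, nor with all rows. Signal over background limits the dimmest genes, for which no detection calls were used.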

Other observations

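All tests in this part were chosen after the results they bear on were seen, except that of the neighbours of Slc2a1. The members of the 4 gene lists added here were also chosen after the changed genes had been seen. Their p-values are therefore descriptive and give no independent support. Further gene groups moved with those described. Aminoacyl-tRNA synthetases of the cytosol, which charge tRNAs for translation and of which the ATF4 list holds some, were higher also outside that list. Of 13 such genes, 3 rose (Yars by 0.75, Lars by 0.58 and Eprs by 0.65 on the log2 scale), 11 had positive log2 fold changes and 0 fell (median 0.41; camera adjusted p = 8.31e-05 over 4 added lists; adjusted p = 0.202 with an estimated correlation). The 16 mitochondrial synthetases had a median of 0.01 and 0 members past limma's test (camera adjusted p = 0.457; 0.537 with an estimated correlation). Replication-dependent histone genes, transcribed in S phase, fell in 3 of 25 cases, H2bc12 by 1.43, H2bc3 by 0.88 and H2ac20 by 0.73 on the log2 scale. Of the 25, 8 had positive log2 fold changes and 0 rose (median -0.33, camera adjusted p = 0.000841, adjusted p = 0.483 with an estimated correlation). Histone genes are near-identical, so probes can be shared between copies. The symbol pattern that defined this list was corrected after a first look, to drop H1f10, a linker histone not tied to replication. The fibroblast and melanocyte marker lists had medians of 0.96 and 0.33 on the arrays of these synthetase and histone values.

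Known targets of the MiT/TFE transcription factors, which control lysosome formation, were higher outside the lysosome list too. Of 20 tested, 5 rose and 0 fell, with Mcoln3 at 2.12, Rragd at 2.05, Gpnmb at 2.04, Ctsk at 1.15 and Gaa at 0.74 on the log2 scale (median 0.35; camera adjusted p = 8.84e-09; adjusted p = 0.184 with an estimated correlation). Gpnmb and Mcoln3 are also expressed by melanocytes and Ctsk by fibroblasts, whose marker lists had medians of 0.33 and 0.96 on the same arrays. The source of these values within the cultures was not tested. Arrdc4, which like Txnip is known to follow glucose metabolites and was chosen after its values were seen, had a log2 fold change of -0.95 with SE 0.170 that did not pass (limma adjusted p = 0.0614).

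The signal of Slc2a1 stayed near the wild-type level on the arrays labelled Glut1-deficient. A swap of 1 array of each group is argued against, since the most similar pair of arrays with different labels differed by an SD of 0.326 over genes, more than the 0.239 and 0.21 of the pairs with the same label. A signal too bright for a fall to show stays open. Of 277 genes within 0.5 log2 of the level of Slc2a1, 9 were lower by 0.5 or more on both arrays, with Thbs1 the largest fall at -1.82, but levels of different probes cannot be set against each other. Probes outside the deleted exons also stay open, as their positions are not known here; the dimmer row changed by -0.519.

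Fibroblast markers were higher on both arrays labelled Glut1-deficient. RNA from fibroblasts in those cultures stays open, because the markers differed together between these 2 arrays (median 0.433 higher on array 1, 13 of 14 markers), a difference that 0% of 10000 random lists matched on level reached. Those lists were not matched on the change from wild type, so that share is not particular to fibroblast RNA. Over all genes, array 1 differed from the wild-type arrays by an SD of 0.396 and 0.383, and array 2 by 0.338 and 0.326. Of the 14 markers, 11 lay above both wild-type arrays on both arrays, while Fbln1 was at -0.61 and Col3a1 at 0.26; how large a share of fibroblasts these values allow was not tested. Fewer keratinocytes with all other cells raised alike stays open. Fibroblast markers differed between the arrays by 0.563 ± 0.479 and melanocyte markers by -0.062 ± 0.280 (SD over markers, permutation p = 0.00078, adjusted p = 0.00117 over 3 tests). Log2 differences cannot decide this, because an equal raise moves markers unequally where their wild-type levels differ. On the linear scale, an equal raise gives all markers the same ratio of excess over wild type between the arrays. The median ratio, array 1 over array 2, was 2.87 (1.23 to 7.26) for fibroblast and 0.901 (0.723 to 1.56) for melanocyte markers with an excess on both. These ranges overlapped, fibroblast markers did not share 1 ratio, and the sets were not tested against each other on that scale. The list medians above wild type were higher on array 1 for both, at 1.18 against 0.66 for fibroblasts and 0.51 against 0.31 for melanocytes. Single melanocyte markers were higher on array 1 in 5 of 11 cases. A change of transcription within keratinocytes is untested and open, and genes are not independent replicates here.

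The rise of the ATF4 list was set against the same cells. RNA from fibroblasts alone is not excluded, because the test takes all fibroblast transcripts to share 1 ratio between these 2 arrays. The permutations shuffled genes, which are not independent replicates, so p measures the spread over genes and not between cultures. The excess over wild type on array 1 relative to array 2 had a median ratio of 1.2 in the ATF4 list and 2.87 among fibroblast markers (permutation p = 2e-05, adjusted p = 6e-05). The medians thus differed, but single ratios ran from 0.912 to 5.78 in the ATF4 list and from 1.23 to 7.26 among fibroblast markers. The fibroblast markers did not share 1 ratio, and the ranges overlapped. These ratios cover the members with an excess on both arrays, 21 of 22, 13 of 14 and, for melanocytes, 7 of 11; a relative difference over all members gave permutation p = 2e-04 against fibroblasts and 0.0905 against melanocytes. For melanocytes alone the ratio was 0.901 (permutation p = 0.0743), and the p missing the threshold leaves them open, as does a mixture of both cell types. The genotype itself stays open as an untested biological explanation, and the lower number of cells lysed goes with it on both arrays.

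A test of genes near Slc2a1, fixed before its result was seen, turned out to be void for strain variants linked to the floxed allele, because both genotypes carry that allele. Of the 200 nearest tested genes, 8 changed (4.0%), against 620 of 21938 others (2.83%; odds ratio 1.43, 95% interval 0.607 to 2.90; Fisher's exact p = 0.284, two-sided).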
